A study of Homo sapiens with 9 samples.

How the data were processed

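RNA sequencing measured gene expression in 9 libraries of Kasumi-1, a human acute myeloid leukaemia cell line that carries the t(8;21) translocation and so makes the AML1-ETO fusion (AE, also RUNX1-RUNX1T1). Per the labels' protocols, cells were infected with shRNA lentiviruses for 48 h and selected with 1 µg/mL puromycin for another 48 h, and total RNA was taken on day 4. Per the labels, 3 libraries carry a control shRNA, 3 carry AE shRNAs numbered 1 to 3, and 3 carry LYL1 shRNAs numbered 538, 540 and 542. The labels do not say whether the AE numbers mark different shRNAs or repeats of 1 shRNA. They also do not say whether the libraries of a group come from separate cultures.

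The deposited files hold 1 raw read count per gene symbol and library, with 59648 genes in each. The deposited counts are whole numbers and carry no normalisation. Per the submitters' processing notes, fastp 0.20.1, HISAT2 2.2.0, SAMtools 1.7, featureCounts 2.0.1, DESeq2 1.26.0 and the genome build hg19 were used, with no role or order given. The sources used here do not give the gene annotation, the strand setting or the treatment of reads that map to several places. Counts of genes with near-identical copies, such as ribosomal protein, histone and tryptase genes, and of overlapping or antisense genes are therefore uncertain. RUNX1 and RUNX1T1 counts add the reads of the fusion to those of the normal genes. No coordinates are given, since no annotation of the files' build was at hand. In 6 of the files 5 gene names carried a trailing decimal suffix, which was removed. Of the 14741 genes tested, 12818 had their symbol in the reference gene table (GRCh38).

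Library totals ranged from 20103275 to 28039518 counts. Counts were scaled with TMM factors and are given as CPM, counts scaled by the library total, as mean ± SD of 3 libraries. Genes were kept with filterByExpr by group. Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with robust dispersions and all 9 libraries in one group-means model. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene is called at an adjusted p below 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Fold changes use edgeR's prior count of 0.125. The 3 comparisons are AE knockdown against control, LYL1 knockdown against control, and AE knockdown against LYL1 knockdown, which tests the difference between the knockdowns as a contrast of the same model, so that the control libraries take part in its estimate of spread. The median standard error of a log2 fold change was 0.22 in the AE comparison and 0.22 in the LYL1 comparison.

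Before the data were examined, 35 gene lists were fixed from textbook knowledge, of which 31 had at least 5 tested members. Each was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Counts of called members are given over all genes tested and adjusted over the list alone. Genes are named by a rule that was also fixed then. It takes the knockdown targets and 5 of their partners. It takes, per knockdown, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2 and no overlap between the groups. It also takes up to 4 members per list with the smallest adjusted p, the genes called in both knockdowns and the 5 largest differences in each direction between the knockdowns. Clone, LOC, pseudogene, antisense and small RNA names and sex-linked marker genes were left out of the rule, which left 11306 genes open to naming. Where another gene is named, the text says so.

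The alternatives were other scalings (median-of-ratios, upper-quartile, library size only), no low-count filter or a strict one (50 counts in 3 libraries), DESeq2 1.42.0, limma-voom, the legacy and non-robust quasi-likelihood tests, fits of only the 6 libraries compared, an adjusted p below 0.01, an added 2-fold minimum, a replicate block and leaving out each library in turn. limma-voom with a spread per group was added after seeing the data. The fit was tested on simulated counts with 200 changed genes among 14741. These counts gave every group the pooled spread of each gene (median dispersion 0.0429). The control, AE and LYL1 libraries alone gave medians of 0.00686, 0.0916 and 0.0398, so the rates below hold for the pooled spread only. In the AE comparison it called 2.99% of the 1.5-fold changes, 50.7% of the 2-fold changes and 93.9% of the 4-fold changes. In the LYL1 comparison it called 2.99%, 41.8% and 92.4%. DESeq2 called more of the changed genes in that comparison (58.2% of the 2-fold changes). It also called more of the 14541 unchanged genes, 19 against 5 for edgeR. Since both comparisons against control share the control libraries, 20 simulations of unchanged libraries gave the values that sharing alone produces. They draw each gene on its own, so their ranges are too narrow for genes that move together. A 3' UTR check used GENCODE v29 transcripts, 1 per gene, and covered 11078 of the 11523 tested genes with a protein-coding reference entry (96.1%).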

Results

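Gene expression was measured by RNA sequencing in 9 libraries of Kasumi-1 cells on day 4 after infection with shRNA lentiviruses, in 3 groups of 3 libraries. The control shRNA libraries held 24658644, 26339032 and 23893891 counts. The AE knockdown libraries held 28039518, 27327089 and 22764565 counts, and the LYL1 knockdown libraries (shRNAs 538, 540 and 542) 25364794, 25372150 and 20103275. Counts varied least between the control libraries, with a biological coefficient of variation of 7.57%, against 31.5% between the AE and 20.9% between the LYL1 knockdown libraries. The first principal component, which held 56.5% of the variance, placed the controls between -31.2 and -30.1, the LYL1 knockdown libraries between -37.6 and -23.2 and the AE knockdown libraries at 46.1, 29.7 and 102. Replicate 3 of the AE knockdown thus lay farthest from the controls, and its scaling factor was 0.914 against 0.997 to 1.04 in the other libraries. Because the labels do not say that the libraries of a group are separate cultures, the p-values measure only the spread between these samples.

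The knockdown targets were read first. RUNX1T1, the ETO part of the fusion, lay at 217 ± 5.89 CPM in the controls and at 113 ± 24.4 CPM with AE knockdown (SD, n = 3), which is 52.6%, 63.0% and 40.5% of the control mean in the 3 libraries. Its log2 fold change was -0.94 (SE 0.18, edgeR adjusted p = 0.00778). RUNX1, whose reads come from the fusion and from the normal allele, fell from 380 ± 11.8 to 224 ± 22.3 CPM (-0.76, SE 0.17, edgeR adjusted p = 0.0119). That call was lost without control replicate 1 (adjusted p = 0.0513) or control replicate 2 (adjusted p = 0.0519). With LYL1 knockdown, RUNX1T1 lay at 215 ± 41.0 CPM and RUNX1 at 426 ± 95.6 CPM, and neither was called (edgeR adjusted p = 1 for each). LYL1 lay at 163 ± 17.0 CPM in the controls and at 80.4, 98.4 and 43.9 CPM with shRNAs 538, 540 and 542, which is 49.5%, 60.5% and 27.0% of the control mean. Its log2 fold change was -1.13 (SE 0.26) and all 3 libraries lay below all 3 controls, but the adjusted p was 0.527 in edgeR and 0.0217 in DESeq2, and from 0.0522 to 1 in the other settings run. LYL1 was not called with AE knockdown (211 ± 46.4 CPM, adjusted p = 0.308), and the difference between the knockdowns was called (log2 difference 1.51, edgeR adjusted p = 0.00553).

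**Figure D1:**
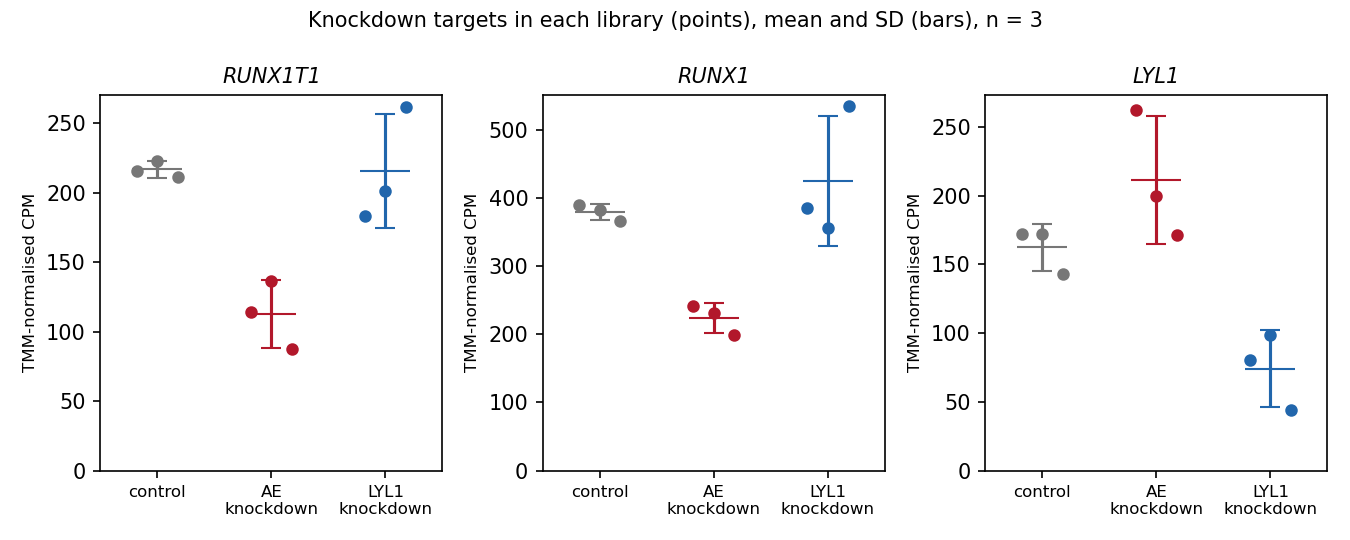
CPM of RUNX1T1, RUNX1 and LYL1 (vertical axes, from 0) in each library, grouped by shRNA; points are libraries and bars show the mean and SD of 3. The AE knockdown libraries lie at 87.7 to 137 CPM for RUNX1T1 against 212 to 223 CPM in the controls, and the LYL1 knockdown libraries at 43.9 to 98.4 CPM for LYL1 against 143 to 172 CPM.

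AE knockdown against control asks which genes depend on the fusion in t(8;21) leukaemia cells. BPI, an antimicrobial protein of neutrophil granules, rose from 18.6 ± 1.84 CPM to 422, 299 and 3645 CPM (log2 fold change 6.29, SE 0.96, edgeR adjusted p = 0.00399). SELPLG, the selectin ligand PSGL-1 of leukocytes, rose 24.8-fold (adjusted p = 0.00224) and LAPTM5, a lysosomal membrane protein of blood cells, rose 14.2-fold (adjusted p = 0.00405). PSTPIP1, CST7, PRAM1, CEACAM6, DHRS9, PLB1 and CD82 completed the 10 largest named rises, at log2 fold changes of 3.42 to 4.41. Among the falls, FLT1, a receptor of vascular endothelial growth factor, went from 25.7 ± 3.47 CPM to 0.0358, 0.564 and 0.0481 CPM (log2 fold change -6.77, SE 0.44, adjusted p = 5.82e-05). ECM1, an extracellular matrix protein, fell 8.47-fold (adjusted p = 0.000321), JCAD, a protein of endothelial junctions, 11.8-fold (adjusted p = 0.000717) and SCUBE1, a secreted and surface protein, 8.87-fold (adjusted p = 0.00327). OLFML2A, CAVIN1, MYRF, ADAMTS15, TUBB4A and GIPC3 were the other named falls, at log2 fold changes of -4.78 to -3.18. Without AE knockdown replicate 3 the log2 fold changes of BPI, SELPLG and LAPTM5 were 4.26, 3.88 and 2.89, and those of PSTPIP1, PRAM1, CEACAM6, DHRS9 and PLB1 lay between 2.30 and 3.08. Without AE knockdown replicate 2 those of FLT1, OLFML2A, CAVIN1 and GIPC3 were -9.12, -5.50, -6.27 and -3.80.

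In all, edgeR called 3214 of 14741 genes with AE knockdown, 1684 higher and 1530 lower, of which 828 and 613 changed at least 2-fold. The 3 AE and 3 control libraries did not overlap for 45.2% of genes, where chance gives 10%. The numbers rest on the 3 control libraries: without control replicate 1, 2 or 3 the calls were 1096, 954 and 1050. Of the 31 lists, camera called 17, 7 higher and 10 lower, of which fry called 9, and none was called with an estimated correlation. Fry did not call the primary granule, late granulocyte, monocyte and macrophage, S phase and MYC lists (fry adjusted p of 0.0529 to 0.126). Nor did it call the heat shock, sterol and adhesion lists (fry adjusted p of 0.0952 to 0.181). All 20 genes named above kept their sign in every fit that left out 1 library. DHRS9 and CD82 lost their call without any 1 of the 3 controls (adjusted p up to 0.0728 and 0.0578), and CAVIN1 lost it without control replicate 2 (adjusted p = 0.0537). Of the 115 genes given by the naming rule that were called, 79, 68 and 74 were called without control replicate 1, 2 or 3, with the same sign in all 115. Their median absolute log2 fold change was 1.42, 1.45 and 1.46 in these fits, against 1.43 with all libraries.

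Genes that the fusion is described as repressing and primary granule genes were higher with AE knockdown. Of 10 genes described as repressed by AE, not all of them genes of myeloid differentiation, 8 rose and 1 fell (8 and 1 adjusted over the list alone). Their median log2 fold change was 2.05 (camera adjusted p = 0.000578, adjusted p = 0.38 with an estimated correlation). SPI1, the transcription factor PU.1, rose from 128 ± 10.8 to 281 ± 76.4 CPM, RASSF2, a RAS effector, rose 4.16-fold and LAT2, a signalling adaptor, 7.19-fold. NF1, a negative regulator of RAS, was the gene that fell (1.71-fold). Of 14 primary granule genes 6 rose and none fell (6 over the list alone, median 0.89, camera adjusted p = 0.00223, adjusted p = 0.494 with an estimated correlation). Besides BPI and CST7 these included PLAC8, at 33.7 ± 1.21 CPM in the controls and 137 ± 87.6 CPM, and RNASE3, a granule ribonuclease, at 0.312 ± 0.188 CPM and 8.98, 2.92 and 41.3 CPM. Without control replicate 1, 2 or 3 there were 3, 3 and 3 calls in this list, and PLAC8 was not among them (adjusted p up to 0.0627).

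Of 10 late granulocyte genes 4 rose and 1 fell (5 and 1 over the list alone, median 0.81, camera adjusted p = 0.028, adjusted p = 0.423 with an estimated correlation). CEBPE, a factor of granulocyte maturation, rose 4.12-fold, and the formyl peptide receptor FPR2 fell 3.89-fold. Of 14 monocyte and macrophage genes 7 rose and none fell (7 over the list alone, median 1.81, camera adjusted p = 0.00555, adjusted p = 0.494 with an estimated correlation). They included CSF1R, the receptor of macrophage colony-stimulating factor (2.86 ± 0.293 CPM to 15.8, 11.9 and 56.3 CPM), TYROBP, an adaptor of myeloid receptors (0.580 ± 0.247 CPM to 10.4, 3.49 and 72.9 CPM), and S100A8, a calcium-binding protein of granulocytes and monocytes (0.0126 ± 0.0218 CPM to 1.29, 2.92 and 85.1 CPM). The highest value of BPI, CEBPE, TYROBP, CSF1R and S100A8 was in replicate 3 of the AE knockdown, the library that stood farthest from the controls. That library also had the lowest RUNX1T1 level (40.5% of the control mean) and the highest share of mitochondrial rRNA (1.21% of counts). Whether either bears on these genes was not tested. Without that library the log2 fold change was 1.38 for CEBPE (2.04 with it) and 2.26 for CSF1R (3.28 with it). Without that library 3 late granulocyte and 5 monocyte and macrophage genes were called higher. Without control replicate 1, 2 or 3 the late granulocyte calls were 3, 2 and 2 and the monocyte and macrophage calls 4, 1 and 3. Those lost without control replicate 2 include CSF1R (adjusted p = 0.0512), TYROBP (0.05) and S100A8 (0.0743).

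Genes of stem and progenitor cells and genes described as raised by the fusion were lower with AE knockdown. Of 18 stem and progenitor genes 7 fell and none rose (7 lower and 1 higher over the list alone, median -0.44, camera adjusted p = 0.00049, adjusted p = 0.336 with an estimated correlation). ERG fell from 215 ± 3.77 to 94.8 ± 31.6 CPM, GATA2 from 72.3 ± 6.16 to 36.3 ± 9.80 CPM and ETV6 from 238 ± 16.9 to 137 ± 29.4 CPM, all transcription factors of blood stem cells. Of 12 genes described as raised by AE 6 fell and none rose (6 over the list alone, median -0.75, camera adjusted p = 0.00049, adjusted p = 0.38 with an estimated correlation), among them JUP (plakoglobin, 2.45-fold), the cyclin CCND2 (2.13-fold) and the phosphatase UBASH3B (2.03-fold). Of 10 components and partners of the AE-containing transcription factor complex 4 fell and none rose (6 lower and 1 higher over the list alone, median -0.59, camera adjusted p = 0.00638, adjusted p = 0.423 with an estimated correlation). RUNX1T1 and RUNX1, the targets of the knockdown, are 2 of these 4, so the test of this list in part restates the knockdown. The others were CBFB, the partner subunit of RUNX1 (1.53-fold), and TAL1 (2.01 ± 0.519 to 0.374 ± 0.356 CPM, log2 fold change -2.33, and -3.42 without AE knockdown replicate 2). The arginine methyltransferase CARM1 lay at 83.1 ± 6.50 CPM in the controls and 50.2 ± 19.0 CPM (adjusted p = 0.0658), TCF3 at 219 ± 7.76 and 148 ± 45.1 CPM (adjusted p = 0.0616), and LMO2 at 108 ± 6.92 and 171 ± 31.2 CPM (adjusted p = 0.0656), none of them called, nor were TCF12 (adjusted p = 0.221) and LDB1 (adjusted p = 0.19). Without control replicate 2 the calls were 3, 2 and 2 in the 3 lists, with ETV6 (adjusted p = 0.055), UBASH3B (0.0519) and TAL1 (0.0683) lost. ETV6 also lost its call without control replicate 1 (adjusted p = 0.0616), and CBFB without control replicate 3 (adjusted p = 0.0537).

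Proliferation, growth and immediate early genes were also lower with AE knockdown. Of 24 AP-1 and immediate early genes 11 fell and none rose (13 lower and 2 higher over the list alone, median -0.87, camera adjusted p = 2.9e-05, adjusted p = 0.423 with an estimated correlation). The AP-1 subunits FOSL2 and FOSL1 fell 2.86-fold and 4.43-fold, and ETV5, a target of RAS-MAPK signalling, 4.36-fold. Of 44 S phase genes 8 fell and none rose (7 over the list alone, median -0.43, camera adjusted p = 1.51e-05, adjusted p = 0.494 with an estimated correlation), led by UHRF1, a factor of DNA methylation upkeep (2.48-fold). Of 51 G2 and M phase genes 13 fell and none rose (14 over the list alone, median -0.29, camera adjusted p = 3.85e-05, adjusted p = 0.494 with an estimated correlation), among them the spindle protein TPX2 (1.74-fold). Of 34 MYC and ribosome biogenesis genes 4 fell and none rose (3 over the list alone, median -0.31, camera adjusted p = 0.000692, adjusted p = 0.512 with an estimated correlation), and the nucleolar proteins NOLC1 and NCL fell 2.18-fold and 2.13-fold, NCL with no call without any 1 control (adjusted p up to 0.079). The share of called MYC genes was near that of all tested genes, of which 1530 of 14741 were called lower. Without control replicate 1, 2 or 3 the calls were 5, 5 and 7 for AP-1, 3, 1 and 1 for S phase, 4, 4 and 4 for G2 and M phase and 2, 2 and 1 for MYC genes, and 7 for AP-1 without AE knockdown replicate 1. Without AE knockdown replicate 2 they were 28 for S phase, 24 for G2 and M phase and 10 for MYC genes, and the MYC list was not called without AE knockdown replicate 3 (camera adjusted p = 0.0676).

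Ribosomal protein and respiratory chain genes were higher with AE knockdown. Of 37 cytosolic ribosomal protein genes 31 rose and none fell (36 over the list alone, median 0.89, camera adjusted p = 5.03e-16, adjusted p = 0.423 with an estimated correlation). RPL13 rose from 520 ± 8.35 to 1115 ± 303 CPM. Genes whose symbol is RPL or RPS with a number took 5.33%, 5.40% and 5.26% of all counts in the controls, 7.81%, 7.86% and 11.8% with AE knockdown and 5.93%, 5.86% and 4.56% with LYL1 knockdown. This set is not the list above, as it can hold pseudogenes named in this way and leaves out genes such as RPLP0 and RPLP2. Of 36 oxidative phosphorylation genes 16 rose and none fell (18 over the list alone, median 0.40, camera adjusted p = 1.35e-05, adjusted p = 0.423 with an estimated correlation). SDHC, a subunit of complex II, rose 1.88-fold and UQCRC1, of complex III, 1.44-fold. The median of each list stayed above 0 under every scaling. A correction of each library for transcript length and GC content took the oxidative phosphorylation list to a median of 0.23 and 6 calls, and the ribosomal protein list to 0.74 and 23 calls. Without control replicate 1, 2 or 3 there were 14, 13 and 11 ribosomal protein and 3, 2 and 3 oxidative phosphorylation calls, and without AE knockdown replicate 3 there were 24 and 12. UQCRC1 lost its call without any 1 control (adjusted p up to 0.0651).

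Stress response and sterol genes were lower and adhesion genes higher with AE knockdown, with less support by camera than most lists above. Of the 4 lists below, fry called only that of unfolded protein and amino acid response genes (fry adjusted p = 0.0153). Of 29 unfolded protein and amino acid response genes 7 fell and none rose (8 lower and 1 higher over the list alone, median -0.35, camera adjusted p = 0.017, adjusted p = 0.38 with an estimated correlation). STC2, a secreted stress-response protein, fell 5.69-fold, PHGDH, of serine synthesis, 2.21-fold and ASNS, asparagine synthetase, 3.04-fold. Of 13 heat shock genes 3 fell and none rose (4 over the list alone, median -0.54, camera adjusted p = 0.0218, adjusted p = 0.494 with an estimated correlation). They included CHORDC1, a co-chaperone of HSP90 (1.59-fold). Of 27 cholesterol and sterol genes 3 fell and 1 rose (none lower and 1 higher over the list alone, median -0.39, camera adjusted p = 0.046, adjusted p = 0.586 with an estimated correlation). The share of sterol genes called lower was near that of all tested genes, 1530 of 14741. Of 22 adhesion and migration genes 10 rose and 2 fell (10 and 2 over the list alone, median 0.71, camera adjusted p = 0.0478, adjusted p = 0.512 with an estimated correlation), led by SELPLG.

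The calls within these 4 lists rest on the control libraries. Without control replicate 1, 2 or 3, none of the stress response, heat shock and sterol genes was called lower, and 2, 1 and 1 adhesion genes were called higher. Without AE knockdown replicate 2 the lower calls were 11, 5 and 8 in the stress response, heat shock and sterol lists. They were 4 stress response genes without AE knockdown replicate 1, 1 heat shock gene without shRNA 538 or 540, 1 sterol gene without AE knockdown replicate 1 or shRNA 540 and none without AE knockdown replicate 3. The heat shock list was not called without AE knockdown replicate 3 (camera adjusted p = 0.126). The sterol list was not called without control replicate 1, AE knockdown replicate 3 or shRNA 542 (up to 0.405), nor the adhesion list without any 1 control, AE knockdown replicate 3 or shRNA 538 (up to 0.127).

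The other 14 lists were not called with AE knockdown, and genes moved both ways in most. Of 21 myeloid transcription factors 7 rose and 1 fell (7 and 2 over the list alone, median 0.21, camera adjusted p = 0.0738), with SPI1, CEBPD and CEBPE the first. Of 28 hypoxia and glycolysis genes 2 rose and 5 fell (2 and 5 over the list alone, median -0.16, camera adjusted p = 0.0929), with the hexokinase HK1 2.52-fold and the glucose transporter SLC2A3 5.22-fold lower, a log2 fold change of -2.38 that was -3.31 without AE knockdown replicate 2. Of 16 cytokine receptors 5 rose and 2 fell (5 and 2 over the list alone, camera adjusted p = 0.457), among them IL6R, which rose from 0.440 ± 0.0397 CPM to 19.1, 3.91 and 64.5 CPM. Of 30 interferon-stimulated genes 5 rose and 2 fell (5 and 3 over the list alone, camera adjusted p = 0.603), with IFITM3 2.56-fold lower. Of 23 p53 pathway genes 2 rose and 6 fell (2 and 6 over the list alone, median 0.11 where camera points down, camera adjusted p = 0.828). Of 25 apoptosis regulators 4 rose and 2 fell (4 and 2 over the list alone, camera adjusted p = 0.414), and of 19 NF-kB and inflammatory cytokine genes 4 rose and 3 fell (4 and 4 over the list alone, camera adjusted p = 0.813). Leaving out any 1 of the 9 libraries moved at least 1 of these counts by over 1.5 times. Over these fits the higher calls ranged from 3 to 7 for myeloid factors, 0 to 2 for hypoxia, 1 to 6 for cytokine receptors, 0 to 6 for interferon genes, 1 to 4 for p53 genes, 1 to 6 for apoptosis and 1 to 5 for NF-kB. The lower calls ranged, in the same order, from 0 to 3, 3 to 9, 1 to 2, 1 to 3, 0 to 6, 0 to 2 and 2 to 4.

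Marker genes of other cell types moved both ways. Of 6 mast cell, basophil and eosinophil markers 1 rose and 2 fell (1 and 2 over the list alone, camera adjusted p = 0.0885, median -0.09 and mean 0.39). The tryptase genes TPSB2 and TPSAB1, near-identical copies, lay at 5.27 ± 0.845 and 1.33 ± 0.204 CPM in the controls and at 0.532 ± 0.122 and 0.294 ± 0.0788 CPM. Of 11 lymphoid markers 1 rose and 2 fell (1 and 2 over the list alone, camera adjusted p = 0.457), with CD3D at 4.24 ± 1.03 and 0.456 ± 0.190 CPM. Of 6 megakaryocyte and platelet markers 1 rose and 1 fell (2 and 1 over the list alone, median 0.16 where camera points down, camera adjusted p = 0.786). Of 13 arginine methyltransferases and acetyltransferase coactivators KAT2B rose and EP300 fell (1 and 1 over the list alone, median 0.09 where camera points down, camera adjusted p = 0.846). KAT2B was not called without any 1 control (adjusted p up to 0.0786), and EP300 not without control replicate 1 or 2 (up to 0.0563). None of 13 mitochondrially encoded genes (median -0.09, mean 0.05, camera adjusted p = 0.825) or 9 replication-dependent histone genes (camera adjusted p = 0.457) was called by edgeR over all genes or over the list alone. Of 14 housekeeping reference genes 2 rose and none fell (2 over the list alone, camera adjusted p = 0.172). There were none without any 1 control and 1 without AE knockdown replicate 1, and RPLP0 lost its call without any 1 control (adjusted p up to 0.0756). Leaving out 1 library moved the counts of the marker, coactivator and histone lists by at most 1 gene. Among lists with under 5 tested members, CD74 of MHC class II rose 2.48-fold and COL6A1 of fibroblasts fell (log2 fold change -1.85), CD74 without a call if any 1 control was left out (adjusted p up to 0.0878) and COL6A1 without control replicate 1 or 2 (up to 0.0814). CIITA, the erythroid markers EPOR, KLF1 and TFRC, and PDGFRB, FN1 and EPCAM were not called.

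**Figure D2:**
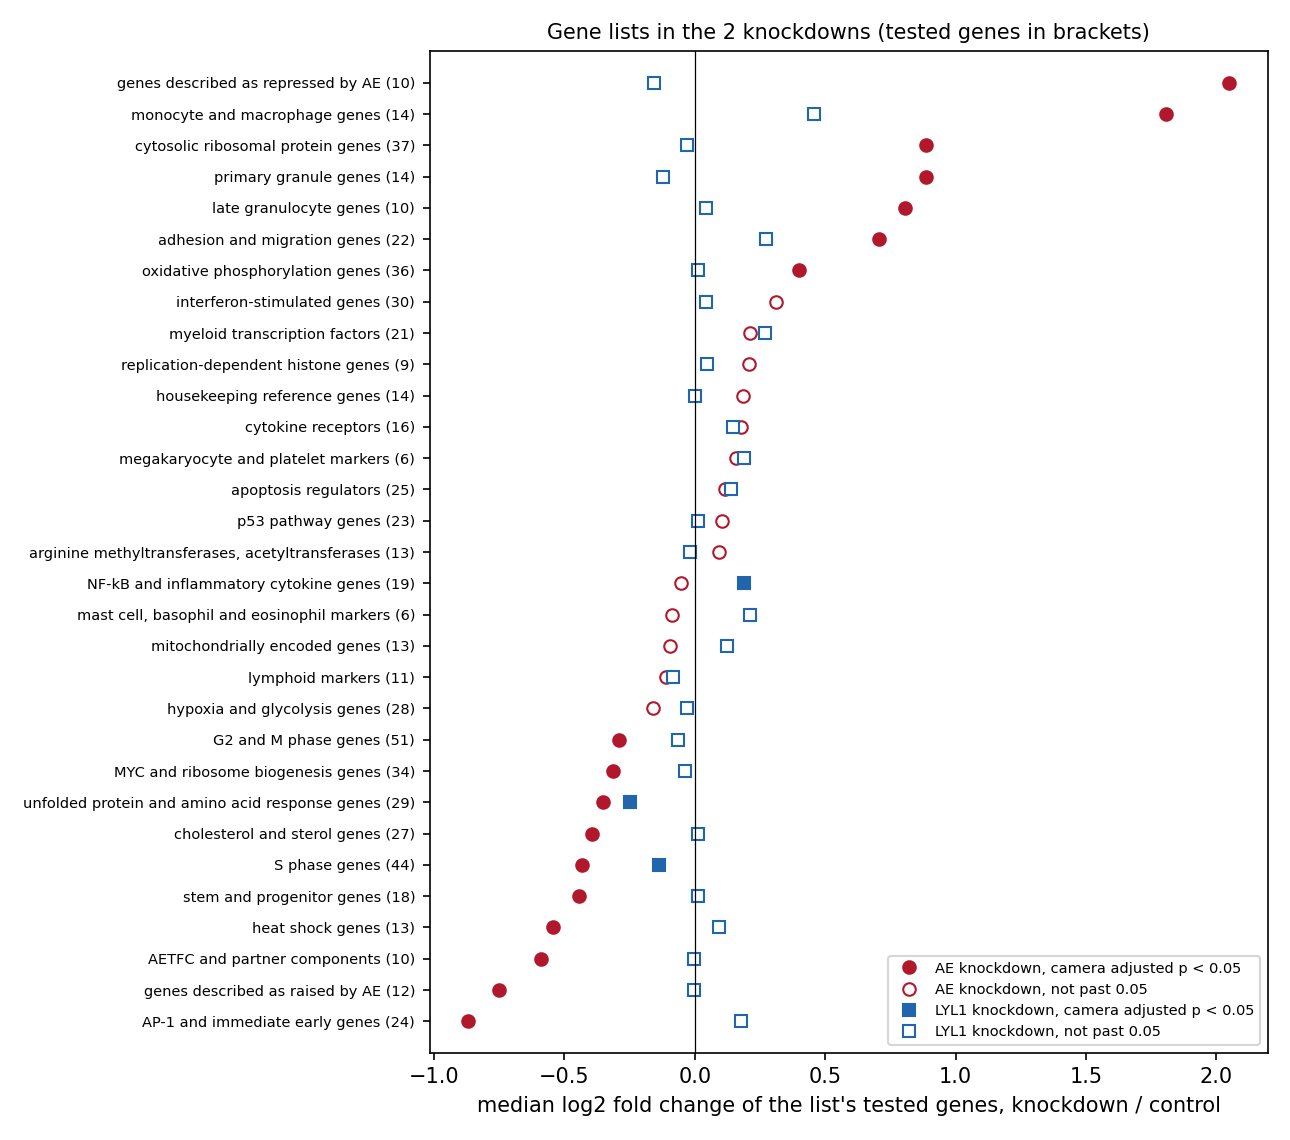
Median log2 fold change against control (horizontal axis) of the tested genes of each of the 31 gene lists, with AE knockdown (red circles) and LYL1 knockdown (blue squares). Filled symbols have a camera adjusted p below 0.05 at the preset correlation, and none passes with an estimated correlation. The AE medians span -0.87 to 2.05 and the LYL1 medians -0.25 to 0.46.

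LYL1 knockdown against control asks which genes depend on LYL1, a transcription factor of the same complex. Few genes were called. HSD17B10, a mitochondrial enzyme and a subunit of mitochondrial RNase P, rose from 13.4 ± 1.17 to 57.3 ± 4.32 CPM (log2 fold change 2.09, SE 0.14, edgeR adjusted p = 0.000107), and was called in each of the 9 fits that left out 1 library. TRH, the thyrotropin-releasing hormone gene, fell from 464 ± 0.927 to 125 ± 40.7 CPM (-1.89, SE 0.23, edgeR adjusted p = 0.0408). TRH was not called without any 1 control, any 1 LYL1 library or AE knockdown replicate 1, with adjusted p up to 0.299. These 2 were the genes called by edgeR, and DESeq2 called 33. In simulated counts of this comparison DESeq2 also called more unchanged genes than edgeR, 19 against 5. At an unadjusted p below 0.05 there were 711 genes, where a uniform p gives 737 and simulated unchanged libraries gave 263 (233 to 285 in 20 simulations). The 3 LYL1 and 3 control libraries did not overlap for 16.6% of genes, where chance gives 10%. Without AE knockdown replicate 1, 2 or 3 the calls were 1, 6 and 11.

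No member of the 31 lists was called with LYL1 knockdown over all genes in the 9-library fit of edgeR, whereas CXCL8, JUND, MDM2 and ICAM1 were called in its fit of only the 2 groups compared (adjusted p = 0.0201, 0.0201, 0.0302 and 0.0369). Camera called 3 lists, fry none. Unfolded protein and amino acid response genes had a median log2 fold change of -0.25, with 24 of 29 below 0 (none called over the list alone, camera adjusted p = 0.000179, adjusted p = 0.0681 with an estimated correlation). PDIA4, a chaperone of the endoplasmic reticulum, lay at 427 ± 4.31 and 301 ± 37.5 CPM (adjusted p = 0.788). S phase genes had a median of -0.14, with 35 of 44 below 0 (none over the list alone, camera adjusted p = 0.00134, adjusted p = 0.964 with an estimated correlation). NF-kB and inflammatory cytokine genes had a median of 0.19 (2 of 19 higher over the list alone, camera adjusted p = 0.0124, adjusted p = 0.377 with an estimated correlation). Their camera adjusted p rose to at most 0.268 when control replicate 3, shRNA 538 or shRNA 542 was left out, each of which ended the call. CXCL8, the neutrophil chemokine interleukin-8, lay at 1.62 ± 0.284 and 6.55 ± 1.64 CPM (edgeR adjusted p = 0.0587) and ICAM1, an adhesion molecule, at 14.4 ± 2.05 and 33.8 ± 7.24 CPM (edgeR adjusted p = 0.596). In the p53 pathway list 3 of 23 genes were higher over the list alone, led by MDM2, the ubiquitin ligase of p53 (39.9 ± 1.45 and 66.9 ± 5.50 CPM, edgeR adjusted p = 0.201 over all genes). Of the other lists, 1 AP-1 gene was higher, 1 mast cell, basophil and eosinophil marker higher and 1 lower, and LYL1 itself lower, over the list alone.

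The comparison of the knockdowns asks whether loss of LYL1 and loss of the fusion act alike. edgeR called 3003 genes between them, 1573 higher and 1430 lower with AE knockdown. The spread behind these calls takes in the control libraries, which varied least. Their coefficient of variation was 7.57%, against 31.5% and 20.9% in the AE and LYL1 libraries, so the count may be too high. limma-voom called 2778 genes, and 1685 with a spread per group. BPI (log2 difference 6.82, SE 0.98), SELPLG (4.66, SE 0.60), CST7 (4.55, SE 0.78), PSTPIP1 (4.14, SE 0.73) and ADAM8, a protease of myeloid cells (3.97, SE 0.71), were the largest named differences above 0. FLT1 (-6.68, SE 0.44), ZFP36L1, an RNA-binding regulator of mRNA decay (-3.92, SE 0.55), OLFML2A (-3.79, SE 0.55), CAVIN1 (-3.71, SE 0.80) and JCAD (-3.49, SE 0.34) were the largest below 0. Of the lists, 15 differed by camera, 6 higher and 9 lower with AE knockdown, and none with an estimated correlation (lowest adjusted p = 0.302). Of 37 ribosomal protein genes 28 were higher with AE than with LYL1 knockdown (35 over the list alone, camera adjusted p = 1.83e-17, adjusted p = 0.534 with an estimated correlation) and of 24 AP-1 and immediate early genes 13 were lower (14 over the list alone, camera adjusted p = 9.19e-07, adjusted p = 0.445 with an estimated correlation). Without shRNA 538, 540 or 542 the ribosomal protein calls were 21, 22 and 13 and the AP-1 calls 8, 9 and 7, and AP-1 calls were 8 without control replicate 1 or 2 or AE knockdown replicate 1. Without shRNA 538, 540 or 542 the calls over all genes were 1830, 2122 and 1467, and a fit of the 6 libraries alone called 941.

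HSD17B10 and TRH were also the genes called in both knockdowns in the same direction. HSD17B10 rose to 89.6 ± 6.11 CPM with AE knockdown (log2 fold change 2.74, edgeR adjusted p = 7.28e-06), more than with LYL1 knockdown (log2 difference 0.65, edgeR adjusted p = 0.0085). TRH fell to 172 ± 32.2 CPM with AE knockdown (-1.43, edgeR adjusted p = 0.00422), and its difference between the knockdowns was not called (0.46, edgeR adjusted p = 0.167). Independent lists would share 0.114 higher and 0.104 lower genes, and no gene was called in opposite directions in the 9-library fit of edgeR or in DESeq2, where edgeR fits of only the 2 groups compared gave 1. TRH was not called with LYL1 knockdown in 7 of the 9 fits without 1 library. Across the 14741 genes, which are not independent replicates, the log2 fold changes of the 2 knockdowns correlated at r = 0.247, where unchanged groups that share the controls gave 0.262 (0.244 to 0.277 in 20 simulations). A second set of simulations redrew all 9 libraries, with the AE group means kept as measured and only the LYL1 group unchanged. There sharing gave 0.0988 (0.0735 to 0.127). The covariance of the 2 knockdowns was 0.0756 against 0.0277 (0.0255 to 0.03) and 0.0267 (0.0202 to 0.0343) in these simulations. The simulations share the controls, but they hold no real deviation common to all 3 controls and no genes that move together. The 3 controls are too few to give each comparison 2 of its own, so part of the excess may come from such a deviation. Genes called higher with AE knockdown had a median log2 fold change of 0.07 with LYL1 knockdown (simulated 0.03 to 0.05) and those called lower -0.08 (simulated -0.02 to 0.00). Over the 3214 genes called with AE knockdown, the slope of the LYL1 knockdown profile on the AE change was 0.124 for shRNA 538 and 0.11 for shRNA 540, but 0.00693 for shRNA 542, the library with the lowest LYL1 level. These genes were picked for their difference from the same controls, which alone favours a slope above 0, and no simulated slope was computed.

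**Figure D3:**
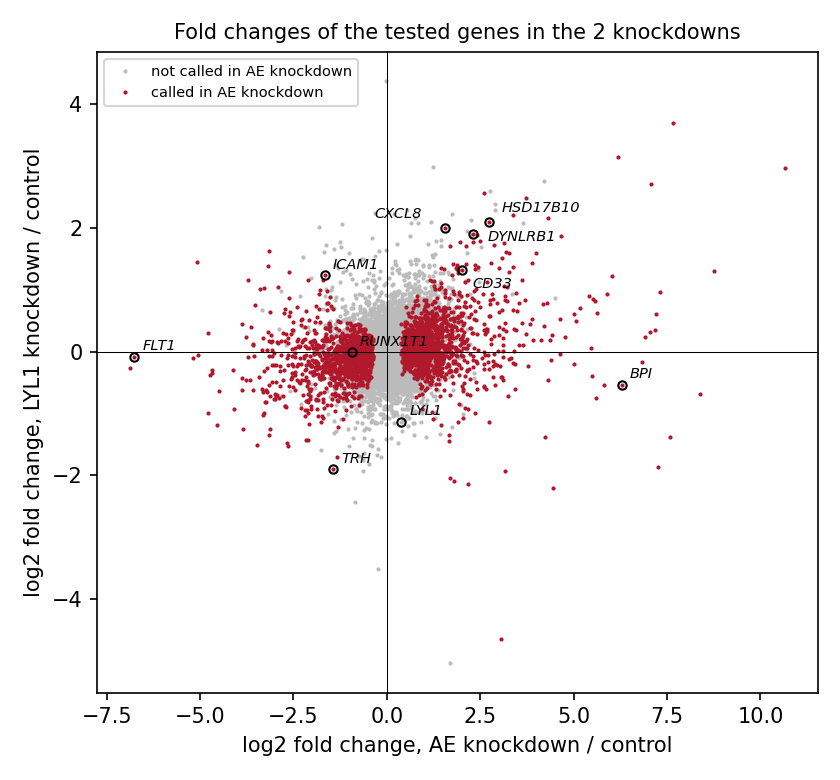
Log2 fold change against control with AE knockdown (horizontal axis) and LYL1 knockdown (vertical axis), 1 point for each of the 14741 tested genes; red points are called with AE knockdown, and circled genes are labelled, of which DYNLRB1 and CD33 were chosen after their values were seen. HSD17B10 lies at 2.74 and 2.09, TRH at -1.43 and -1.89, and BPI and FLT1 at 6.29 and -6.77 on the horizontal axis.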

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

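The screen below was narrowed after the values were seen, to genes of the naming rule whose 3 AE and 3 LYL1 knockdown libraries lay on opposite sides of all 3 controls and whose difference between the knockdowns passed the test. All values are the AE minus the LYL1 log2 fold change, tested in edgeR as the contrast of the 2 knockdowns.

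In 13 genes the knockdowns moved apart in this way. Passing the test of the difference was part of the screen, so the adjusted p-values below are no separate support. With AE knockdown above and LYL1 knockdown below the controls were ADAM8, a protease of myeloid cells (3.97, adjusted p = 0.00686), PLAC8, listed with the primary granule genes (3.10, adjusted p = 0.00387), and IFITM1, an interferon-stimulated membrane protein (1.37, adjusted p = 0.00691). The ribosomal protein gene RPLP2 (0.93, adjusted p = 0.00553), the lysosomal enzyme GUSB (0.80, adjusted p = 0.0363) and UQCRC1 of respiratory complex III (0.71, adjusted p = 0.00457) were the others.

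With AE knockdown below and LYL1 knockdown above the controls were GIPC3 (-3.49, adjusted p = 0.00119), the adhesion molecules ICAM1 (-2.90, adjusted p = 0.00196) and CD44 (-1.15, adjusted p = 0.00333), and the glucose transporter SLC2A3 (-2.58, adjusted p = 0.00603). The phosphatase DUSP1 (-1.21, adjusted p = 0.00607), the transcription factor POU4F1 (-0.79, adjusted p = 0.0045) and the mitophagy receptor BNIP3L (-0.62, adjusted p = 0.0101) were the others. None of the 13 was called for the LYL1 knockdown against control by edgeR, where their adjusted p lay between 0.596 and 1, and BNIP3L (0.119) and GUSB (0.101) were not called for the AE knockdown. ICAM1 was called higher with LYL1 knockdown in the edgeR fit of only the 2 groups compared (1.23, adjusted p = 0.0369) and in limma-voom with a spread per group (1.21, adjusted p = 0.0308), and in no other setting run. Against control, their unadjusted edgeR p with LYL1 knockdown ran from 0.00255 (ICAM1, log2 fold change 1.23) to 0.644 (SLC2A3, 0.20). A difference between the knockdowns may thus rest mainly on the AE knockdown and need not mean opposite responses. No explanation was tested for these genes.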

How the results depend on the processing

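The limma-voom fit with a spread per group was chosen after seeing the data, and the other settings before the data were examined. No called value changed its direction in any setting.

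With AE knockdown 1684 genes were higher and 1530 lower. An adjusted p below 0.01 left 375 and 438 and a 2-fold minimum 828 and 613, as fewer genes pass by construction. A replicate block gave 647 and 792, but the replicate numbers do not pair the samples, with correlations of 0.042, -0.013 and 0.007 between the control and AE libraries of like number. Leaving out 1 library gave 423 to 2335 higher and 531 to 1932 lower, where the lowest counts came without a control and the highest without AE knockdown replicate 2.

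With LYL1 knockdown 1 gene was higher and 1 lower. Higher genes were 4 by library size only, 7 with no low-count filter, 24 in DESeq2, 11 in the fit of only the 2 groups compared and 19 in limma-voom with a spread per group. Lower genes were 0 with the strict filter or an adjusted p below 0.01, 9 in DESeq2, 4 in the fit of only the 2 groups compared and 6 in limma-voom with a spread per group. Leaving out 1 library gave 1 to 9 higher and 0 to 2 lower. Fits whose spread leaves out the AE libraries gave more calls, and the cause of the other changes was not tested.

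Between the knockdowns 1573 genes were higher with AE knockdown and 1430 lower. The fit of only these 2 groups gave 470 and 471, an adjusted p below 0.01 gave 371 and 413, a 2-fold minimum 754 and 601, and limma-voom with a spread per group 814 and 871. Leaving out 1 library gave 662 to 2151 higher and 805 to 1856 lower. Fits whose spread rests less on the controls, those of only these 2 groups and with a spread per group, gave fewer calls. The first of these also has fewer libraries. Without a spread per group limma-voom gave 1357 and 1421. The cause of the other changes was not tested.

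In both knockdowns 1 gene was higher and 1 lower. Higher in both were 4 by library size only, 6 with no low-count filter, 12 in DESeq2, 7 in fits of only the 2 groups compared, 9 in limma-voom with a spread per group and 1 to 8 with 1 library left out. Lower in both were 0 with the strict filter or an adjusted p below 0.01, 4 in DESeq2, 2 in fits of only the 2 groups compared, 2 in limma-voom with a spread per group and 0 to 2 with 1 library left out. In opposite directions was 1 gene in fits of only the 2 groups compared and 1 in limma-voom with a spread per group, where the other settings gave 0. The correlation of the 2 knockdowns across genes went from 0.247 to 0.358 with no low-count filter, which adds genes with few counts, and to 0.153 to 0.312 with 1 library left out. The cause was not tested.

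RUNX1T1 with AE knockdown kept its call except under the 2-fold minimum, which its log2 fold change of -0.94 does not reach. RUNX1 (-0.76) was not called at an adjusted p below 0.01 or with a 2-fold minimum, nor without control replicate 1 or 2, and lay between -0.82 and -0.70 with 1 library left out. LYL1 with LYL1 knockdown was called in DESeq2 alone (-1.14, adjusted p = 0.0217), over a range of 0.0217 to 1. Of the other values 6589 kept their side of the threshold, 407 were no longer past it and 63 came past it. The 6589 include values that changed direction but were past the threshold in neither fit. The replicate block was run for the AE comparison only, since the LYL1 libraries carry shRNA numbers. The depth of 20103275 to 28039518 counts limits genes under about 1 CPM, whose fold changes depend on the prior count.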

Other observations

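Tests chosen only after the result was seen were those of a control shRNA effect, of the level of the neighbouring genes, of AE knockdown replicate 3 alone and of the spread taken from the AE libraries, the leading set and all later tests of the word GTCGCCC, and the screen of gene families. The Alu test was chosen after the word ranking was seen but before its own values.

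The other splits of the libraries are too few to test the counts of called genes. Each comparison has 10 splits of its 6 libraries, so no share under 0.05 can be reached. In each, 1 split, the real one, called as many genes as the real one (3214, 2 and 3003), and the highest count of the other splits was 0.

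HSD17B10 was higher in both knockdowns than in the control libraries, and DYNLRB1 (log2 fold change 2.30 with AE and 1.90 with LYL1 knockdown), named after its values were seen, was higher in both as well, without a call for LYL1 knockdown (edgeR adjusted p = 0.0587). Reads from a neighbouring gene would need that gene to rise. RIBC1, the nearest on 1 side, had log2 fold changes of 0.992 with AE and 1.24 with LYL1 knockdown (largest absolute value 1.239). The AE value fell just short of the bound set in advance, which applied to both knockdowns. RIBC1 reached at most 0.960 CPM, however, where the smaller rise of HSD17B10 was 43.8 CPM. The nearest gene that reaches this level, HUWE1, was not higher in either knockdown (highest log2 fold change -0.196), which argues against reads from it.

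An effect of the control shRNA may instead have lowered HSD17B10 in the controls, which would raise it alike in both knockdowns. Of 23 genes higher with LYL1 knockdown at an unadjusted p below 0.001, 19 were above 0 with AE knockdown and 11 called, with a median AE minus LYL1 difference of -0.443, between the bounds set for and against. These genes were picked for their difference from the same controls, which alone favours like signs and a value below 0, and no value without change was computed, so this decides nothing. A shared response to both knockdowns, and a control effect, cannot be told apart by this value, since all control libraries carry a control shRNA and the design has no other control. HSD17B10 also differed between the knockdowns (log2 difference 0.65, edgeR adjusted p = 0.0085), which a control effect alone would not give.

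A seed match to the control shRNA in 3' UTRs was tested over 15494 words of 7 bases. The first with LYL1 knockdown was GTCGCCC, in 474 genes that include HSD17B10, with a mean log2 difference of 0.11 (adjusted p = 7.88e-10). With AE knockdown it did not pass, which the test required (0.10, SE 0.039, adjusted p = 0.473, unadjusted p = 0.0119 in the same test). The AE minus LYL1 difference was small (-0.015, SE 0.038). An effect in the controls would raise both knockdowns. In the 329 genes where the word is followed by A the mean was 0.09 (SE 0.02) with LYL1 and 0.13 (SE 0.05) with AE knockdown, and in the 145 others, which include HSD17B10, 0.15 (SE 0.04) and 0.01 (SE 0.08). Its 7 bases occur in Alu repeats, but with LYL1 knockdown the variants GTTGCCC and GTCACCC gave at most 0.014. That argues against a change of all genes with an Alu in the LYL1 comparison. With AE knockdown these variants gave 0.052 (SE 0.025) and 0.03 (SE 0.026), so such a change stays open there. A seed match to the control shRNA is neither shown nor excluded by these values, as the control sequence is not given in the sources used here and genes are not independent replicates.

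Ribosomal protein genes were higher with AE knockdown. A correction of each library for transcript length and GC content left a median of 0.737 (interquartile range 0.335) from 0.887 (0.373), with 23 of 37 genes called from 31, which argues against this bias as the whole cause. Oxidative phosphorylation genes went from a median of 0.40 to 0.23 and from 16 to 6 calls under it, so part of that change may come from length and GC content. Without replicate 3 of the AE knockdown 24 ribosomal protein genes were called, so the change is not in that library alone, although its median was 1.32 against 0.62 and 0.58 in the others. Reads shared with pseudogenes were not tested, and an effect of the knockdown itself stays open as untested.

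Few genes were called for the LYL1 knockdown. The fit of the 6 control and LYL1 libraries called 15 genes, so the spread of the AE libraries may hide some, although leaving out AE knockdown replicate 1 alone gave 1 call. Simulated 2-fold changes were called in 41.8% of cases, so changes of this size could be missed at the pooled spread that was simulated. That spread is above the one between the controls, so the rate does not isolate the number of libraries. The 3 shRNAs' profiles against the control mean had a covariance of 0.0493, above the highest value of 0.0243 of simulated unchanged libraries, the bound set in advance. The simulations draw each gene on its own, and genes that move together would widen that range. An effect of the control shRNA would add to the covariance too, so this value does not settle whether the shRNAs share a change. The LYL1 level of 27.0% to 60.5% of control leaves an effect of partial knockdown open, as untested.

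A screen of 124 families of gene symbols gave 10 by camera for AE knockdown, none with an estimated correlation (adjusted p of at least 0.765). Beyond ribosomal protein genes, COMMD genes were higher (7 of 10 called, adjusted p = 0.000178), as were COX genes of respiratory complex IV and their assembly (10 of 20, adjusted p = 0.000675). Kinesins of the KIF family were lower (12 of 31, adjusted p = 0.000178). For LYL1 knockdown 2 families passed by camera, HSD genes (median 0.08, adjusted p = 0.00342, adjusted p = 0.58 with an estimated correlation), of which HSD17B10 was the 1 called, and MCM genes (median -0.25, adjusted p = 0.041, adjusted p = 1 with an estimated correlation), of which none was called.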
